A study of Mus musculus with 11 samples.

How the data were processed

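Single-cell RNA sequencing was done on CD45 positive cells sorted from whole brain of 11 female mice aged 22 weeks (5.5 months), 1 library per animal. Per the labels' protocols, the animals were perfused with PBS, and the brain cells passed a Percoll gradient before sorting by FACS. The mice were 5XFAD animals that carry human TREM2 on a bacterial artificial chromosome, either the common variant (CV) or the R47H variant. Each had received an acute dose of the TREM2 antibody AL002c or of an isotype control. The groups held 2 CV AL002c, 2 CV isotype, 4 R47H AL002c and 3 R47H isotype animals. Replicates are named by the animal number in the sample titles. The last number of the titles restarts at 1 for animals 48, 49, 53 and 54, all of them R47H. Animals 1 to 10 are therefore called numbering run A and the other 4 numbering run B, although the labels name no batch. No paired analysis was possible because no animal number links an AL002c animal to an isotype animal.

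Per the submitters' processing notes, reads were processed with Cell Ranger 3.1.0 and the builds mm10 and hg38, and the notes do not state which build served for which step. The deposited tables of the 11 animals hold UMI counts for 31053 genes in 47445 barcodes. A further table deposited by the authors holds UMI counts for 20358 genes in the 31948 barcodes they kept as microglia. Its metadata give each barcode's total counts, the percent of mitochondrial UMIs, a sex, and 1 of 12 cluster numbers, whose method is not stated. The highest percent of mitochondrial UMIs was 9.9 in that deposited column. The microglia table held 0 mitochondrial genes, so the list of mitochondrially encoded genes could not be tested. A search of the tables for the human gene TREM2 found 0 entries.

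UMI counts were summed per animal over all microglia. Genes were kept by filterByExpr on the 4 groups, which left 12876, and libraries were scaled by TMM. A quasi-likelihood model with the 4 groups and the numbering run as terms was fitted to all 11 animals at the same time in edgeR 4.0.16 (R 4.3.3). It gave 5 contrasts: AL002c against isotype averaged over both genotypes, in CV mice and in R47H mice, the difference between those genotype-specific effects, and R47H against CV averaged over both antibodies. A gene was called at a false discovery rate of 0.05 (Benjamini-Hochberg, 2-sided). Levels are in CPM, given as the mean with the SD, and changes are log2 fold changes with their SE from the model. Effects within a stratum (CV, R47H run A, R47H run B) came from a model with a term for each group and run. Positions are from the GRCm38 annotation.

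Gene lists were tested by camera in limma 3.58.1 with a preset correlation of 0.01 between genes, adjusted over the 22 lists with at least 3 tested members. Camera with an estimated correlation and fry were run beside it. The lists were homeostatic microglia, disease-associated microglia (DAM) stages 1 and 2, type I interferon response, MHC classes I and II, S phase, G2 and M phase, cytokines and chemokines, glycolysis, nuclear-encoded oxidative phosphorylation, cholesterol synthesis, lipid handling, lysosome, phagocytic receptors (with Fc and complement receptors), TREM2 and DAP12 signalling, Myc and nucleolar targets, integrated stress response, antioxidant response, immediate early and dissociation genes, nuclear-retained RNAs as a sign of RNA quality, and ribosomal protein genes. Marker lists of 14 cell types were tested in the same way as a family of their own.

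Shares of cells were compared between AL002c and isotype within strata of genotype and run, as a difference of means weighted by the number of animals. The test was an exact 2-sided permutation within the strata, with 108 arrangements and a smallest possible p of 0.00926. Within CV, 2 against 2 animals cannot go below 0.167, and within R47H the smallest p is 0.0556. A share of microglia with a UMI of Mki67 or Top2a was taken after each cell was thinned at random to 2000 UMIs. This left out 95 CV AL002c, 61 CV isotype, 1295 R47H AL002c and 704 R47H isotype cells with fewer. Clusters 10 and 11 counted as cycling, since at least 3 of their 10 leading genes were cycle genes. Changes within a cluster were tested by the same edgeR model in clusters with at least 20 cells in every animal of at least 3 groups and in 1 or more of the other, without animals below 20. The 47445 barcodes of all tables were also clustered here (scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, 2000 variable genes, 30 principal components, 15 neighbours, resolution 1). The resulting 43 clusters were named from the marker lists. The doublet caller did not work on these tables, as it called 50 of 47445 barcodes (0.105%), so no doublet was removed. Exact 95% binomial intervals cover counting error only.

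The groups, contrasts, tests, lists and the rule for naming genes were fixed before the data were examined. That rule takes Trem2, the 12 largest rises and 12 largest falls per contrast among called genes with a mean log2 CPM of at least 4, up to 4 members per list with the smallest p in the averaged contrast, and 9 genes of interest. For the averaged contrast, it requires 1 direction in CV, R47H run A and R47H run B. Outside the rule, and chosen after their values were seen, were S100a8 and S100a9, the genes that describe a cluster, and these list members: Mrc1, Myc, Ciita, Cxcl13, Hexa, Ccl6, Nfkbia, Itgax, Cd9, Lyz2, Timp2, C1qa, Egr1, Ccl9, Ifitm3, Mcm5, Dtl, Crybb1, Mthfd2 and Mylip. Alternatives planned in advance were DESeq2 1.42.0, DESeq2-type size factors in edgeR, no filter on low counts, a minimum mean log2 CPM of 4, no term for the run, run A only, no cycling clusters, at least 1000 UMIs per cell, log odds of shares, other clustering resolutions (0.5 and 2) and each animal left out in turn. Alternatives without clusters 4, 8 and 9, without clusters 7, 9, 10 and 11, without cluster 3, and without cells that carry markers of other immune cells were added after the data were seen. Clusters 7, 9, 10 and 11 were picked because they had grown with AL002c. Further added alternatives were shares without thinning, an edgeR test of cell counts per cluster, the list tests under DESeq2-type size factors and clusters rebuilt without their defining genes.

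The procedure was tested on simulated data, with 200 genes changed by 1.5-, 2- or 4-fold among 12667. The averaged contrast recovered 82.1%, 82.1% and 98.5% of them, the CV contrast 53.7%, 70.1% and 90.9%, and the R47H contrast 74.6%, 82.1% and 98.5%. Unchanged genes were called 11, 7 and 24 times in these contrasts. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and matplotlib 3.10.9 served for the remaining steps.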

Results

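Microglia of 11 female 5XFAD mice, an amyloid model, were profiled after an acute dose of AL002c, an antibody that binds human TREM2, or of an isotype control. TREM2 is a lipid-sensing receptor of microglia, and its R47H variant is a risk allele for Alzheimer disease that weakens ligand binding. The groups were CV AL002c (2 animals), CV isotype (2), R47H AL002c (4) and R47H isotype (3). Run A libraries held 8098267 to 24570176 UMIs and run B libraries 44880061 to 69878472. The authors' microglia made up 58.7% to 73.5% of the barcodes of an animal, with 753 to 2507 cells per animal in run A and 4034 to 7902 in run B. The median depth per microglial cell was 7125 to 8018 UMIs in run A and 5549.5 to 6367.5 in run B.

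Mouse Trem2 (ENSMUSG00000023992, chromosome 17, 48346401 to 48354147) was detected at similar levels in all groups. Its mean was 213.5 ± 7.25 CPM (SD, n = 2) in CV AL002c, 215.2 ± 31.0 (n = 2) in CV isotype, 202 ± 15.9 (n = 4) in R47H AL002c and 209 ± 16.5 (n = 3) in R47H isotype microglia. Neither the antibody (log2 change -0.04, adjusted p = 0.752) nor the genotype (0.05, adjusted p = 0.767) passed the test for Trem2. Human TREM2 had no entry in the tables, so its expression was not analysed here. The first principal component of the libraries carried 44.4% of the variance and separated run B from run A, and the second carried 12.04%. Within R47H mice, 4758 of the 12876 tested genes differed between the runs, 2478 of them higher in run B. Haemoglobin transcripts, a sign of blood, reached 1104 CPM in the microglia of CV AL002c animal 1 and 1329 CPM in R47H isotype animal 53, and 51.1 CPM or less in the other 9 animals. The neutrophil transcripts S100a8 and S100a9 together stood at 885.0 CPM in R47H AL002c animal 48, 815.2 in R47H isotype animal 49 and 404.9 in R47H isotype animal 53.

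The first comparison asked what AL002c did to microglia of both genotypes on average. Genes of cell division showed the largest rises. Mki67 (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361), a marker of cells in cycle, rose by 1.60 ± 0.08 (log2, SE; adjusted p = 3.48e-07). Its mean was 23 ± 0.820 CPM in CV AL002c (n = 2) against 10.9 ± 0.966 in CV isotype mice (n = 2), and 82.9 ± 64.9 in R47H AL002c (n = 4) against 23.5 ± 15.5 in R47H isotype mice (n = 3). Top2a (ENSMUSG00000020914, chromosome 11, 98992943 to 99024189), the topoisomerase that untangles replicated DNA, rose by 1.37 ± 0.14 (adjusted p = 7.3e-05). Cdc20 (ENSMUSG00000006398, chromosome 4, 118432901 to 118437352), an activator of the anaphase-promoting complex, rose by 1.81 ± 0.16 (adjusted p = 2.07e-05), and the kinetochore motor gene Cenpe (ENSMUSG00000045328, chromosome 3, 135212537 to 135273611) by 1.79 ± 0.08 (adjusted p = 1.98e-07). All 4 were higher in 10 of the 10 pairs of an AL002c and an isotype animal of the same genotype and run. For Mki67 the effect within strata was 1.07 in CV, 2.31 in R47H run A and 2.10 in R47H run B. Falls were smaller, led by the galectin gene Lgals3 (ENSMUSG00000050335; -0.60 ± 0.11, adjusted p = 0.00801), which was higher in 0 of 10 pairs. The purinergic receptor gene P2ry13, a homeostatic marker (-0.19 ± 0.03, adjusted p = 0.00631), the translation factor genes Eif3j1 (-0.22 ± 0.04, adjusted p = 0.0121) and Eif1a (-0.20 ± 0.04, adjusted p = 0.0219) and the nuclear RNA Malat1 (-0.14 ± 0.03, adjusted p = 0.0448) also fell. In all, 254 genes rose and 27 fell by edgeR, with 1891 genes at an unadjusted p under 0.05 against 643.8 that chance would give. The count of 281 was 2 without a term for the run, 71 in run A alone, 107 among genes with a mean log2 CPM of at least 4. It was 731 without the filter on low counts, 110 without clusters 10 and 11, and 11 without clusters 7, 9, 10 and 11. Clusters 7, 9, 10 and 11 were picked because they had grown with AL002c, so a lower count without them is partly built into the choice. The count was 156 without CV AL002c animal 5 and 169 without CV isotype animal 3.

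**Figure D1:**
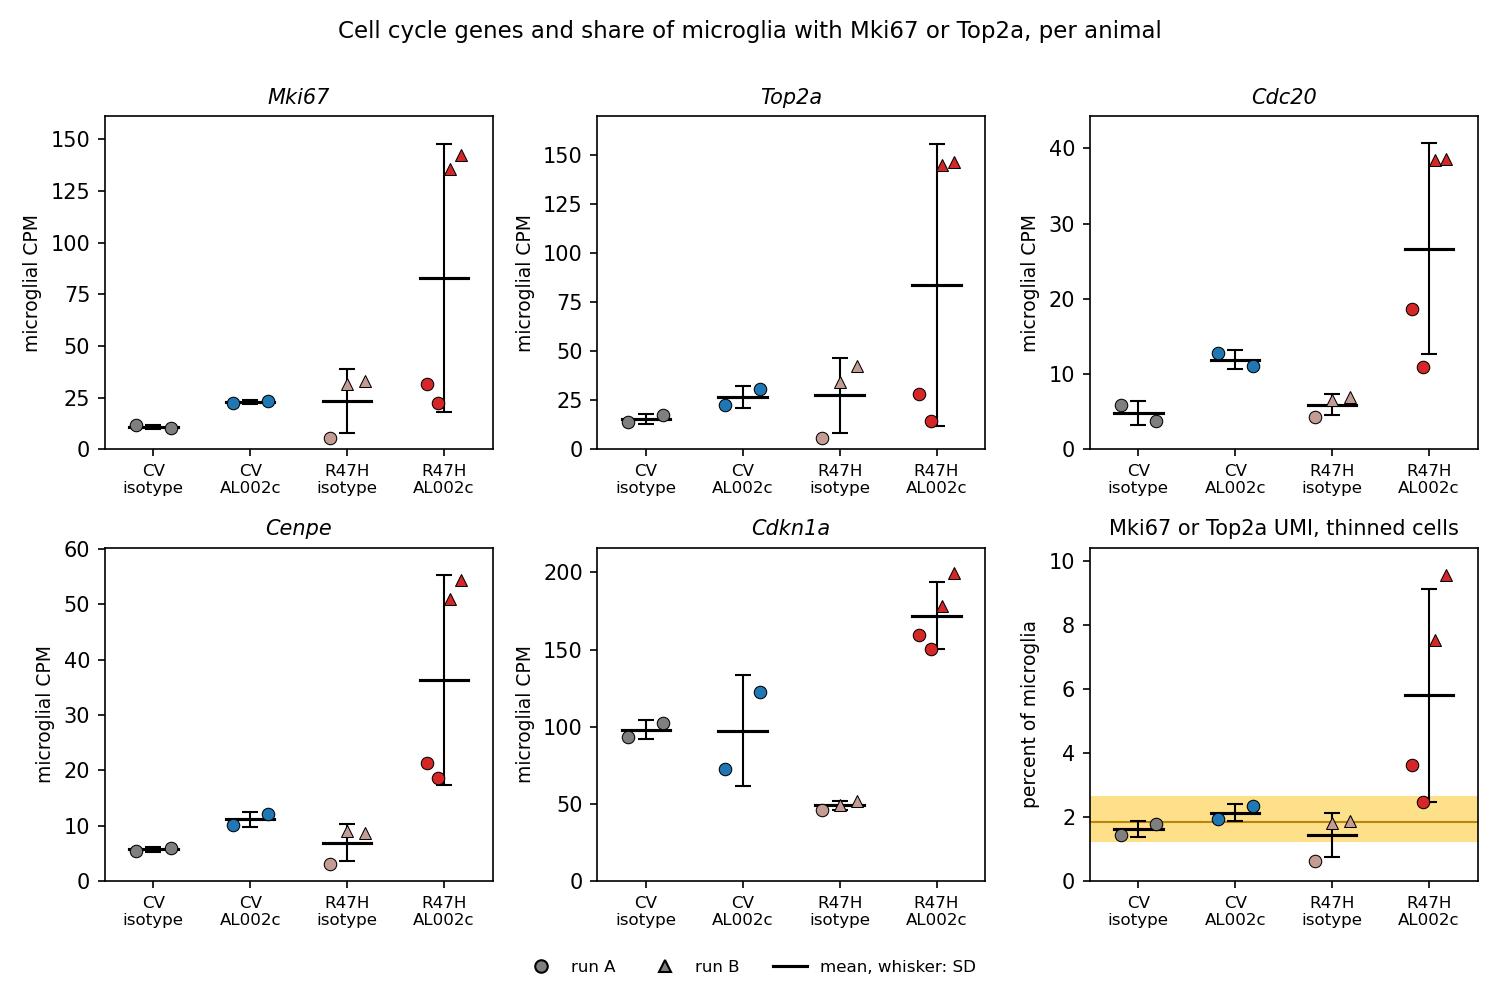
CPM per animal (y axis) of Mki67, Top2a, Cdc20, Cenpe and Cdkn1a in the 4 groups, and in the last panel the percent of thinned microglia with a UMI of Mki67 or Top2a, with the share in neutrophil-like cells of all animals, mostly of run B, as a line and its exact 95% interval as a band. Circles are run A animals, triangles run B animals, bars the group means and whiskers the SD; Mki67 was higher with AL002c in 10 of 10 pairs of animals within genotype and run.

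By list, averaged over the genotypes, 41 of the 50 tested G2 and M phase genes rose and 0 fell (45 higher when adjusted over the list alone), with a median log2 change of 1.37. Camera gave an adjusted p of 4.71e-70 for that list, and the adjusted p = 0.0567 with an estimated correlation. S phase genes rose in 6 of 42 cases, for example Brip1, a DNA repair helicase (1.62 ± 0.23, adjusted p = 0.00119). Of the same 42, 10 were higher and 1 lower over the list alone (camera adjusted p = 8.92e-08; adjusted p = 0.305 with an estimated correlation). Without clusters 10 and 11 the S phase list turned to the opposite direction and was called lower (median -0.05, camera adjusted p = 0.0178), and without clusters 7, 9, 10 and 11 it was not called (0.331). Both settings leave out cluster 10, which is led by replication genes such as Mcm6 and Mcm5. The loss of the rise is therefore partly built into them and is no separate test of it. Of 30 type I interferon response genes, 11 rose and 0 fell (21 higher over the list alone, median 0.37, camera adjusted p = 2.74e-18; adjusted p = 0.236 with an estimated correlation). They included the ubiquitin-like modifier Isg15 (0.47 ± 0.07, adjusted p = 0.00279), Ifit3 (0.54 ± 0.09, adjusted p = 0.00499) and Ifi27l2a (1.30 ± 0.17, adjusted p = 0.000948). Among 9 MHC class II genes, which present antigen to CD4 T cells, H2-Ab1 rose (0.47 ± 0.11, adjusted p = 0.0360), and 7 were higher over the list alone (median 0.47, camera adjusted p = 2.33e-05; adjusted p = 0.236 with an estimated correlation). Of 22 cytokine and chemokine genes 3 rose (4 over the list alone): Il1b, the gene of interleukin-1 beta (0.74 ± 0.10, adjusted p = 0.00125), Cxcl16 (0.32 ± 0.06, adjusted p = 0.0183) and Ccl12 (0.29 ± 0.06, adjusted p = 0.0277). The camera adjusted p of the cytokine list was 0.00115, and the adjusted p = 0.236 with an estimated correlation.

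Of 80 ribosomal protein genes 9 rose, such as Rps19 (0.18 ± 0.03, adjusted p = 0.00684), and 33 were higher over the list alone (median 0.08, camera adjusted p = 1.19e-13; adjusted p = 0.519 with an estimated correlation). Of 74 nuclear-encoded oxidative phosphorylation genes 0 passed by edgeR, and 6 were higher over the list alone (median 0.06, camera adjusted p = 8.94e-08; adjusted p = 0.519 with an estimated correlation). Of 13 MHC class I genes, Tap1, the antigen peptide transporter, rose (0.23 ± 0.05, adjusted p = 0.0143), as it also did over the list alone (median 0.09, camera adjusted p = 0.000789; adjusted p = 0.519 with an estimated correlation). Lysosomal genes rose in 2 of 32 cases, Psap (0.16 ± 0.03, adjusted p = 0.0168) and the cathepsin gene Ctsh (0.18 ± 0.04, adjusted p = 0.0226), and 8 were higher and 1 lower over the list alone (camera adjusted p = 0.0246; adjusted p = 0.544 with an estimated correlation). Camera called 2 lists lower, although 0 of their members passed by edgeR or over the list alone. These were Myc and nucleolar targets (27 genes, median -0.05, camera adjusted p = 0.0187; adjusted p = 0.524 with an estimated correlation) and immediate early and dissociation genes (25 genes, median -0.06, camera adjusted p = 0.0285; adjusted p = 0.524 with an estimated correlation). The latter were not called without CV isotype animal 3 (camera adjusted p = 0.185). Not called were the lists of homeostatic microglia (camera adjusted p = 0.0527; P2ry13 the 1 member of 25 that fell, and 1 higher and 4 lower over the list alone), glycolysis (0.0527), phagocytic receptors (0.173; Fcgr4 rose by 0.36 ± 0.07), cholesterol synthesis, integrated stress response and antioxidant response (0.370 each), DAM stage 1 (0.474), lipid handling (0.717), DAM stage 2 (0.815), TREM2 and DAP12 signalling (0.947) and RNA quality (0.951). Over all contrasts, 12 of 110 list tests had a median, mean and direction of the test that differed in sign, and 0 of these 12 were called. None of the 14 marker lists of cell types was called (smallest camera adjusted p = 0.197). The border-associated macrophage gene Mrc1 rose on its own (0.79 ± 0.13, adjusted p = 0.00495).

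In CV mice, cell cycle genes had positive log2 changes, but no gene passed the test with 2 animals per group. Mki67 changed by 1.07 ± 0.15 (adjusted p = 0.0760), Cenpe by 0.98 ± 0.15 (adjusted p = 0.117) and Ifit3 by 0.54 ± 0.15 (adjusted p = 0.582). Cdkn1a, the gene of the cell cycle inhibitor p21, stood at 97.5 ± 35.7 CPM with AL002c and 98.1 ± 6.31 with isotype (SD, n = 2 each). By edgeR 0 genes were called, with 768 at an unadjusted p under 0.05, and DESeq2 called 15. The edgeR count was 166 without the filter on low counts, 2 without CV AL002c animal 5, 2 without CV isotype animal 3, 6 without CV isotype animal 4, 1 without R47H AL002c animal 7 and 2 without R47H AL002c animal 8. Camera called 8 lists. The G2 and M phase list was higher (median 0.71, adjusted p = 4.34e-31; adjusted p = 0.373 with an estimated correlation), and 27 of its 50 genes were higher over the list alone. Interferon genes (median 0.24, adjusted p = 8.13e-05) and S phase genes (median 0.18, adjusted p = 0.00194) were also higher as sets. Without clusters 10 and 11, which were chosen for their cycle genes, the S phase list was lower (median -0.10, adjusted p = 0.0442). DAM stage 2 (median -0.09) and glycolysis (-0.10; adjusted p = 0.00194 for both), Myc targets (-0.06, adjusted p = 0.00512) and immediate early and dissociation genes (-0.10, adjusted p = 0.000325) were lower. CV isotype animal 3 stood apart in heat shock genes of that list, with 316.0 CPM of Hspa1a against 37.3 to 38.1 in the other 3 CV animals, and without it the list was not called (adjusted p = 0.106). The adjusted p = 0.676 with an estimated correlation for these 6 lists. Ribosomal protein genes were lower with a median of -0.01 (adjusted p = 0.0411; adjusted p = 0.942 with an estimated correlation). In these 7 lists 0 genes passed over all genes, and 1 S phase gene higher, 1 lower and 1 immediate early or dissociation gene lower passed over the list alone. Without CV isotype animal 3 camera called 3 lists, and without CV AL002c animal 5 it called 5. Marker lists moved as well in CV mice: monocyte markers were lower (median -0.78, adjusted p = 0.00590), border-associated macrophage (0.49, adjusted p = 0.0433) and oligodendrocyte markers (0.24, adjusted p = 0.00590) higher, and erythroid markers higher (adjusted p = 0.00453). Each of these 4 was lost with an estimated correlation, with an adjusted p = 0.359, 0.359, 0.233 and 0.393 in that order. The erythroid rise rested on CV AL002c animal 1, at 595.3 CPM of Hbb-bs against 0 in the other 3 CV animals.

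In R47H mice AL002c moved more genes. Mki67 rose by 2.14 ± 0.09 (adjusted p = 8.11e-09), Cenpe by 2.60 ± 0.09 (adjusted p = 2e-09) and Hmmr (ENSMUSG00000020330), which codes for a spindle-associated hyaluronan receptor, by 2.64 ± 0.11 (adjusted p = 8.11e-09). Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727) rose by 1.85 ± 0.13 (adjusted p = 1.18e-06), from 49.1 ± 3.04 CPM in isotype (n = 3) to 172.0 ± 21.9 in AL002c mice (n = 4). Ifi27l2a rose by 2.16 ± 0.22 (adjusted p = 2.96e-05), the antigen-presentation chaperone gene Cd74 by 1.08 ± 0.14 (adjusted p = 0.000371) and Ramp1 (ENSMUSG00000034353), a co-receptor of the calcitonin gene-related peptide receptor, by 1.02 ± 0.06 (adjusted p = 2.83e-07). Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188), the main lipoprotein of microglia near plaques, fell by 0.46 (± 0.09, adjusted p = 0.00723), from 2033 ± 207 CPM in isotype (n = 3) to 1430 ± 280 in AL002c mice (n = 4). The homeostatic genes P2ry13 (-0.36 ± 0.04, adjusted p = 6.72e-05), P2ry12 (-0.23 ± 0.04, adjusted p = 0.00151) and Slc2a5 (-0.25 ± 0.04, adjusted p = 0.000903) fell. In all, 729 genes rose and 224 fell by edgeR (953, with 2708 at an unadjusted p under 0.05). Within runs, 128 rose and 18 fell in run A (2 AL002c animals against isotype animal 10 alone, assumed to vary like the others), and 553 rose and 92 fell in run B, while 0 genes differed in effect between the runs by edgeR (856 at an unadjusted p under 0.05). Of the genes that rose, 540 of 729 (74.1%) were also positive in CV mice, against 51.3% of all genes. Of those that fell, 57.6% were also negative, against 48.7% of all genes. The haemoglobin genes Hbb-bs and Hbb-bt were among the lower genes: Hbb-bs stood at 263.5 ± 441 CPM in isotype and 0.413 ± 0.699 in AL002c microglia (n = 3 and 4), and animal 53 held most of it. The count of 953 was 64 without a term for the run, 145 in run A alone, 593 at a mean log2 CPM of at least 4, 86 without clusters 7, 9, 10 and 11, 589 without R47H AL002c animal 54, 493 without R47H isotype animal 49 and 595 without R47H isotype animal 53.

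In R47H mice camera called 10 lists, and all 10 were lost with an estimated correlation. Of 50 G2 and M phase genes 45 rose and 0 fell (47 higher over the list alone, median 1.98, adjusted p = 4.11e-66; adjusted p = 0.0655 with an estimated correlation). Of 42 S phase genes 13 rose (21 over the list alone, adjusted p = 6.04e-07; adjusted p = 0.294 with an estimated correlation). Without clusters 10 and 11, which were chosen for their cycle genes, the S phase list was not called and its median was -0.05 (adjusted p = 0.214). Interferon response genes rose in 18 of 30 cases (24 over the list alone, median 0.54, adjusted p = 1.44e-19; adjusted p = 0.136 with an estimated correlation). Of 9 MHC class II genes 7 rose (7 over the list alone, median 0.73, adjusted p = 3.74e-06; adjusted p = 0.136 with an estimated correlation), among them H2-Ab1 (0.73 ± 0.12) and Ciita, the master regulator of class II genes (1.46 ± 0.38). Of 13 MHC class I genes 3 rose, namely H2-K1, B2m and Tap1 (4 over the list alone, adjusted p = 0.00120; adjusted p = 0.511 with an estimated correlation). Of 22 cytokine and chemokine genes 7 rose, including Il1b (1.12 ± 0.13), the interferon-induced Cxcl10 (1.17 ± 0.24) and the B cell attractant Cxcl13 (2.78 ± 0.62). In this list, 11 were higher and 1 lower over the list alone (adjusted p = 2.98e-06; adjusted p = 0.0853 with an estimated correlation). Ribosomal protein genes rose in 45 of 80 cases (57 over the list alone, median 0.16, adjusted p = 5.83e-31; adjusted p = 0.219 with an estimated correlation). Of 74 oxidative phosphorylation genes 20 rose (34 over the list alone, median 0.11, adjusted p = 1.46e-13; adjusted p = 0.294 with an estimated correlation). Of 32 lysosomal genes 6 rose, among them Ctsc, Psap and Hexa (10 higher and 1 lower over the list alone, adjusted p = 0.0104; adjusted p = 0.567 with an estimated correlation). Homeostatic genes fell in 7 of 25 cases and rose in 1, P2ry6 (2 higher and 8 lower over the list alone, median -0.06, adjusted p = 0.000423; adjusted p = 0.0853 with an estimated correlation). The DAM lists were not called (stage 1 adjusted p = 0.382, stage 2 adjusted p = 0.0544), although Cd52 (0.81 ± 0.07), Ctsl and Ccl6 of stage 2 rose. Also not called were phagocytic receptors (adjusted p = 0.171, 2 higher and 2 lower), cholesterol synthesis (0.130, Sc5d lower) and Myc targets (0.438, Myc higher and Srm lower). The same held for integrated stress response (0.531), antioxidant response (0.635, Fth1 higher), and RNA quality (0.856, Malat1 lower). It also held for lipid handling with Apoe lower, glycolysis with Aldoa lower, TREM2 and DAP12 signalling and immediate early and dissociation genes with Nfkbia higher (0.978 each). No marker list was called in R47H mice (smallest adjusted p = 0.117, erythroid cells).

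**Figure D2:**
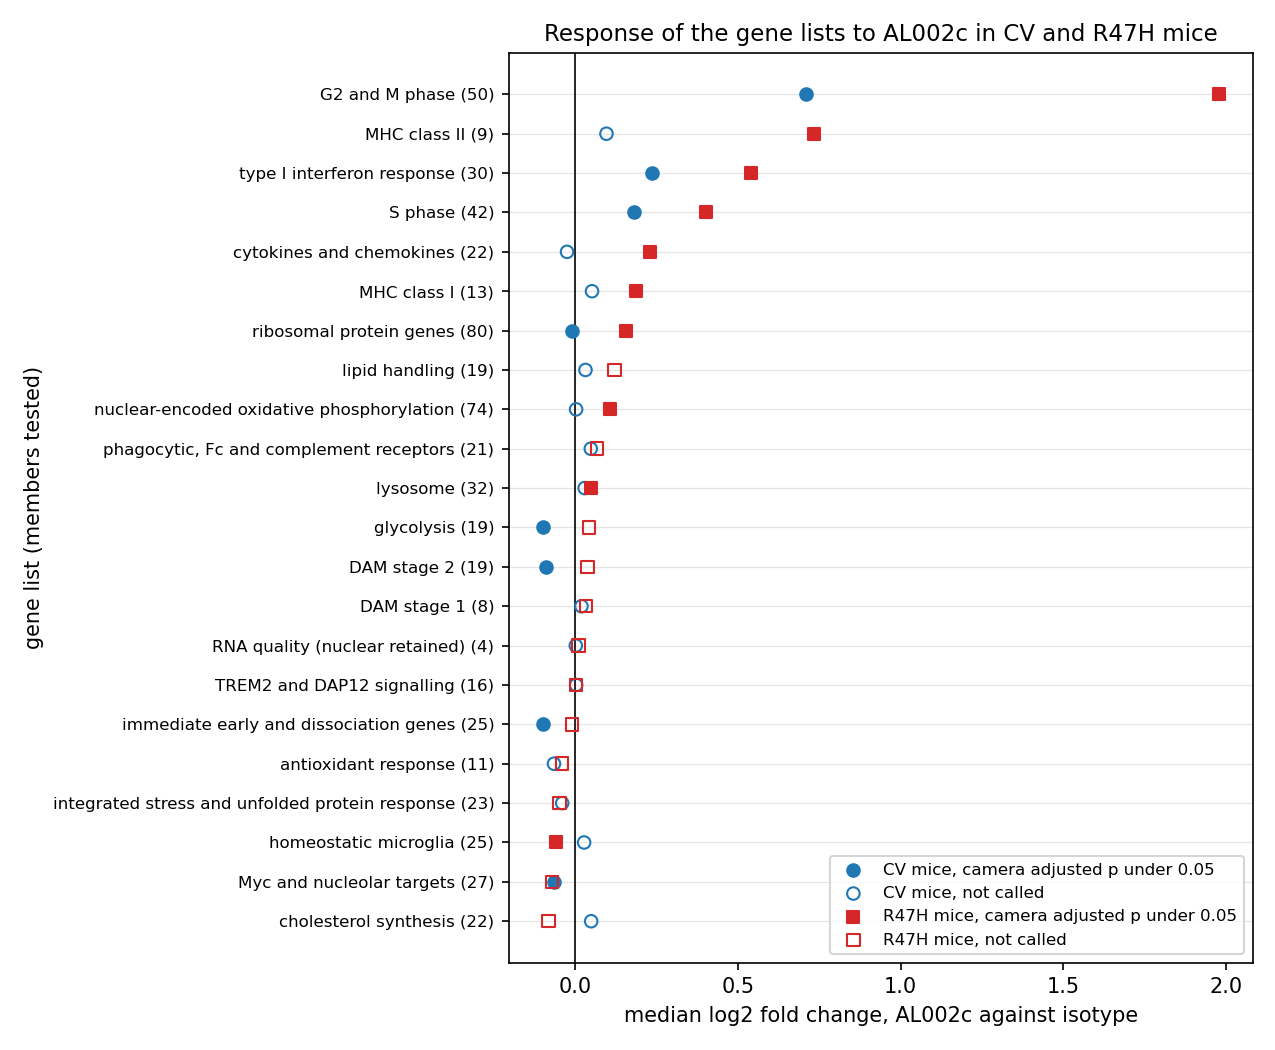
Median log2 fold change (x axis) of AL002c against isotype for each of the 22 gene lists (y axis), with circles for CV mice and squares for R47H mice, filled where camera gave an adjusted p under 0.05. The G2 and M phase list lies farthest to the right in both, at 0.71 in CV and 1.98 in R47H mice.

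Whether the antibody effect differed by genotype was tested directly. All 37 genes called by edgeR had a larger effect in R47H mice, 0 had a smaller one, and 1271 had an unadjusted p under 0.05. Cdkn1a had a difference of 1.85 ± 0.22 (adjusted p = 0.00202), Hmmr 1.85 ± 0.26 (adjusted p = 0.00977), Cenpe 1.62 ± 0.19 (adjusted p = 0.00202), the centromeric histone gene Cenpa 1.59 ± 0.18 (adjusted p = 0.00202) and Mki67 1.08 ± 0.18 (adjusted p = 0.0262). Outside the cycle, Ramp1 (0.93 ± 0.10, adjusted p = 0.00202), Cd52, a surface glycoprotein gene of the DAM stage 2 list (0.82 ± 0.12, adjusted p = 0.00996), Cxcl16 (0.79 ± 0.13, adjusted p = 0.0262) and Tmsb10, which codes for an actin-binding peptide (0.94 ± 0.16, adjusted p = 0.0274), were called. Ramp1 stood at 139.9 ± 3.40 CPM in CV AL002c (n = 2), 131.9 ± 16.9 in CV isotype (n = 2), 188.6 ± 9.54 in R47H AL002c (n = 4) and 93.8 ± 4.40 in R47H isotype mice (n = 3). Cdkn1a and Ramp1, both leading genes of cluster 7, were higher in each R47H AL002c animal than in any CV animal. A larger effect did not always mean this. Cxcl16 was at 63.9 to 75.0 CPM in R47H isotype, 99.9 to 119.3 in R47H AL002c and 114.8 to 135.9 in CV animals. For Cd52 these ranges were 290.5 to 393.6, 551.2 to 652.7 and 487.7 to 590.0 CPM. Top2a was not called for the difference (1.12 ± 0.29, adjusted p = 0.165). DESeq2 called 109 genes, 12 of them lower. The edgeR count was 1 without a term for the run, 23 in run A alone, 21 without clusters 10 and 11, 8 without clusters 4, 8 and 9, 0 without clusters 7, 9, 10 and 11 and 379 without the filter on low counts. It was 12 without CV AL002c animal 1, 22 without CV AL002c animal 5, 13 without CV isotype animal 4, 16 without R47H AL002c animal 54 and 18 without R47H isotype animal 49.

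Camera called 10 lists for this difference, 9 of them higher. G2 and M phase genes were higher in 7 of 50 cases and in 34 over the list alone (median 1.11, adjusted p = 6.36e-31; adjusted p = 0.128 with an estimated correlation). Ribosomal protein genes were higher in 2 of 80 cases and 47 over the list alone (median 0.19, adjusted p = 2.64e-31; adjusted p = 0.317 with an estimated correlation). Of the DAM stage 2 genes Cd52 and Ccl6 were higher, also over the list alone (adjusted p = 7.88e-05; adjusted p = 0.431 with an estimated correlation). Of the cytokines Cxcl16 was higher, with 4 over the list alone (adjusted p = 2.11e-05; adjusted p = 0.128 with an estimated correlation). No gene of the interferon list passed over all genes, and 4 did over the list alone (adjusted p = 8.23e-07; adjusted p = 0.461 with an estimated correlation). The same held for MHC class II with 1 such gene (adjusted p = 0.00427; adjusted p = 0.431 with an estimated correlation) and immediate early and dissociation genes with 2 (adjusted p = 0.00985; adjusted p = 0.461 with an estimated correlation), the latter not called without CV isotype animal 3 (adjusted p = 0.264). Oxidative phosphorylation (adjusted p = 6.54e-09; adjusted p = 0.461 with an estimated correlation) and glycolysis (adjusted p = 0.0409; adjusted p = 0.597 with an estimated correlation) were called with 0 genes passing either way. Homeostatic genes were lower, with 0 of 25 passing and 7 lower over the list alone (median -0.07, adjusted p = 5.3e-05; adjusted p = 0.128 with an estimated correlation). Among marker lists, microglia (-0.12, adjusted p = 0.0110; adjusted p = 0.222 with an estimated correlation), oligodendrocyte (-0.38, adjusted p = 0.0219; adjusted p = 0.222 with an estimated correlation) and erythroid markers (adjusted p = 0.000161; adjusted p = 0.391 with an estimated correlation) were lower. Most haemoglobin transcripts lay in CV AL002c animal 1 and R47H isotype animal 53, on which the erythroid call rests. Monocyte markers were higher (1.01, adjusted p = 0.0162, and 0.424 with an estimated correlation).

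The genotype comparison asked how R47H microglia differed from CV microglia on average over both antibodies. It rested on run A, with 3 R47H against 4 CV animals. Part of the genes of the disease-associated state and of MHC class I were lower in R47H (8 of 19 DAM stage 2 and 7 of 13 class I genes), while both lists were lost with an estimated correlation (adjusted p = 0.0975 and 0.110). Pdcd1 (ENSMUSG00000026285, chromosome 1, 94038305 to 94052553), which codes for the checkpoint receptor PD-1, stood at 40.0 ± 0.194 CPM in CV AL002c (n = 2), 40.1 ± 2.01 in CV isotype (n = 2), 8.88 ± 1.63 in R47H AL002c (n = 4) and 10.1 ± 2.88 in R47H isotype microglia (n = 3), a difference of -2.40 ± 0.12 (adjusted p = 2.73e-07). Axl (ENSMUSG00000002602, chromosome 7, 25757273 to 25788705), a receptor for dead cells, differed by -1.58 ± 0.14 (adjusted p = 8.7e-05), Apoe by -0.78 ± 0.10 (adjusted p = 0.000684) and the lipoprotein lipase gene Lpl by -0.82 ± 0.12 (adjusted p = 0.00250). Spp1, the gene of osteopontin, differed by -2.71 ± 0.47 (adjusted p = 0.00839), with 91.5 ± 87.5 CPM in CV isotype mice (n = 2). H2-Q7 (ENSMUSG00000060550; -1.34 ± 0.16, adjusted p = 0.000509) and H2-Q6 (-1.33 ± 0.16, adjusted p = 0.000761) are near-identical class I genes, so reads can be shared between them. H2-K1 (-0.64 ± 0.07, adjusted p = 0.000461) and H2-D1 (-0.61 ± 0.08, adjusted p = 0.00201) were lower as well. Among the higher genes were the chemokine gene Ccl7 (0.73 ± 0.10, adjusted p = 0.00178), Mtss1 (ENSMUSG00000022353, chromosome 15, 58941234 to 59082005; 0.47 ± 0.05, adjusted p = 0.000220) and the guanylate-binding protein gene Gbp7 (0.53 ± 0.09, adjusted p = 0.00924). In all, 102 genes were higher and 256 lower in R47H by edgeR (358, with 2085 at an unadjusted p under 0.05). The count was 874 without the filter on low counts, 165 without CV AL002c animal 1, 196 without CV isotype animal 4, 143 without R47H AL002c animal 7, 204 without R47H AL002c animal 8 and 150 without R47H isotype animal 10. Without cluster 3, led by Spp1, Lpl and Apoe, 274 genes were called, 252 of them shared with the 358.

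**Figure D3:**
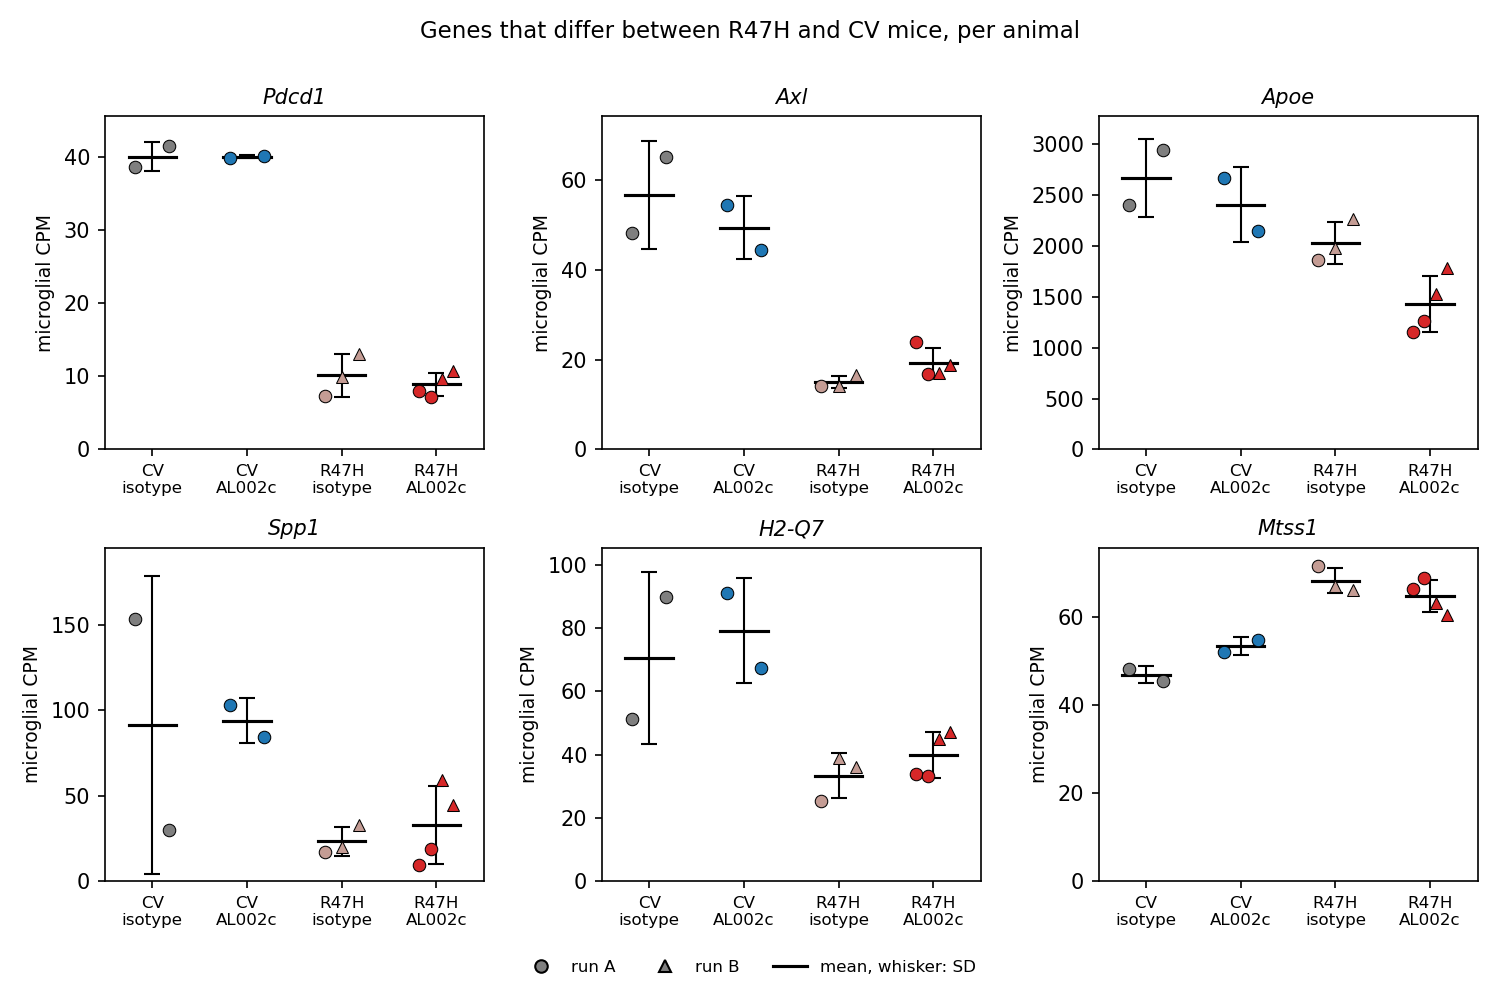
CPM per animal (y axis) of Pdcd1, Axl, Apoe, Spp1, H2-Q7 and Mtss1 in the 4 groups, with circles for run A animals, triangles for run B animals, bars for the group means and whiskers for the SD. Pdcd1 averages 40.0 and 40.1 CPM in the CV groups and 8.88 and 10.1 CPM in the R47H groups.

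By list, camera called 16 for the genotype, and all 16 were lost with an estimated correlation. Of 19 DAM stage 2 genes 8 were lower in R47H, among them the integrin gene Itgax (-1.18 ± 0.09), Cd9 (-0.29 ± 0.03) and Csf1 (-0.54 ± 0.11), and 15 were lower over the list alone (median -0.34, adjusted p = 7.39e-13; adjusted p = 0.0975 with an estimated correlation). Of 8 stage 1 genes 5 were lower, Apoe, B2m, Fth1, Lyz2 and Timp2 (6 over the list alone, adjusted p = 1.63e-07; adjusted p = 0.110 with an estimated correlation). MHC class I genes were lower in 7 of 13 cases (9 over the list alone, adjusted p = 1.39e-10; adjusted p = 0.110 with an estimated correlation). H2-DMa was the 1 of 9 class II genes that was lower (3 over the list alone, adjusted p = 0.00790; adjusted p = 0.281 with an estimated correlation). Phagocytic receptors were lower in 6 of 21 cases, such as Fcgr4 and the complement gene C1qa (1 higher and 9 lower over the list alone, adjusted p = 2.67e-05; adjusted p = 0.0975 with an estimated correlation). Immediate early and dissociation genes were lower in 9 of 25 cases, among them Egr1 (-0.47) and Nfkbia (-0.53), and in 11 over the list alone (adjusted p = 1.3e-08; adjusted p = 0.0975 with an estimated correlation). Of 22 cytokine genes Ccl7 was higher and 5 were lower, among them Ccl9 and Ccl12 (1 higher and 8 lower over the list alone, adjusted p = 2.92e-05; adjusted p = 0.0975 with an estimated correlation). Ribosomal protein genes were lower in 5 of 80 cases (1 higher and 26 lower over the list alone, median -0.09, adjusted p = 2.05e-13; adjusted p = 0.281 with an estimated correlation). Ifitm3 was the 1 interferon gene that was lower (9 over the list alone, adjusted p = 1.39e-06; adjusted p = 0.281 with an estimated correlation).

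Further lists were lower in R47H with few members called. S phase had Mcm5 and Dtl (3 over the list alone, adjusted p = 1.3e-08; adjusted p = 0.191 with an estimated correlation). G2 and M phase had Top2a (3 over the list alone, adjusted p = 2.92e-05; adjusted p = 0.403 with an estimated correlation). In run A, Top2a stood at 28.3 and 14.7 CPM in R47H AL002c against 22.7 and 30.5 in CV AL002c animals. R47H isotype animal 10 stood at 5.99 against 13.7 and 17.3 in CV isotype animals. For Mki67 these values were 31.4 and 22.4 against 22.4 and 23.6, and 5.56 against 11.6 and 10.2. Both genes were thus clearly lower in R47H only with isotype, where animal 10 stands alone in run A. Cholesterol synthesis was lower as a set (median -0.11, adjusted p = 0.00790; adjusted p = 0.281 with an estimated correlation). Myc targets had Myc (6 over the list alone, adjusted p = 0.000438; adjusted p = 0.281 with an estimated correlation). Of 4 RNA quality genes, Kcnq1ot1 (-0.28) and Xist (-0.24) were lower, also over the list alone (adjusted p = 0.00956; adjusted p = 0.233 with an estimated correlation). Homeostatic genes were higher, with Crybb1 (0.45 ± 0.07) and Slc2a5 (0.16 ± 0.04) passing and 5 higher over the list alone (adjusted p = 0.000423; adjusted p = 0.0975 with an estimated correlation). Oxidative phosphorylation was higher with 0 of 74 genes passing either way (adjusted p = 0.0229; adjusted p = 0.639 with an estimated correlation). Not called for the genotype were lysosome (adjusted p = 0.0519), integrated stress response (0.245, Mthfd2 lower), glycolysis (0.297), lipid handling (0.404, Apoe and Lpl lower and Mylip higher), TREM2 and DAP12 signalling (0.836) and antioxidant response (0.880, Fth1 lower). TREM2 and DAP12 signalling was not called in any of the 5 contrasts. Without a term for the run, or without R47H isotype animal 10, oxidative phosphorylation turned to the opposite direction, and S phase, G2 and M phase and RNA quality did so without the term for the run. Border-associated macrophage markers were higher in R47H (median 0.60, adjusted p = 0.0227; adjusted p = 0.355 with an estimated correlation). Mrc1 passed by itself (0.96, adjusted p = 0.00629). T cell markers were lower (-1.16, adjusted p = 0.0230; adjusted p = 0.671 with an estimated correlation) with 0 passing.

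Cycling cells were then counted per animal. After thinning to equal depth, 2.14% ± 0.273 of CV AL002c (SD, n = 2), 1.61% ± 0.251 of CV isotype (n = 2), 5.80% ± 3.33 of R47H AL002c (n = 4) and 1.44% ± 0.698 of R47H isotype microglia (n = 3) held a UMI of Mki67 or Top2a. The share was 3.29 points higher with AL002c across strata, and higher in 10 of 10 pairs (exact permutation p = 0.00926, 2-sided, the smallest it can give). It was 3.04% against 0.633% in R47H run A and 8.56% against 1.84% in R47H run B. A share for comparison came from neutrophil-like cells of the same tables, in the 2 such clusters without cycle genes among their leading genes. It was 1.85% (exact 95% interval 1.26 to 2.61, 1678 cells). Few cycle transcripts were thus partly a condition of the choice. The median depth of these cells before thinning was 8482 UMIs against 6149 in microglia. Of these cells 85.9% came from run B, where the share was 1.73% (1.13 to 2.55, 1441 cells), against 2.53% (0.935 to 5.43, 237 cells) in run A. The run A interval held the mean shares of both CV groups and of R47H AL002c mice of run A, and the run B interval that of R47H isotype but not that of R47H AL002c mice of run B. Within CV the difference was 0.523 points (exact permutation p = 0.333, 2-sided, the smallest possible with 2 against 2 animals). Within R47H it was 4.87 points (exact permutation p = 0.0556, the smallest possible). The share of microglia in the authors' clusters 10, led by the replication genes Mcm6 and Mcm5, and 11, led by Top2a and Mki67, was 3.33% ± 0.134, 1.77% ± 0.249, 4.60% ± 2.01 and 2.60% ± 0.666 in the 4 groups in the same order. That share was 2.04 points higher with AL002c and higher in 10 of 10 pairs (exact permutation p = 0.00926, 2-sided, the smallest it can give). All 10 leading genes of cluster 11 and 4 of those of cluster 10 were themselves called higher in R47H mice, so this share is no separate line of evidence from those genes. Cluster 9 also carried cycle transcripts, with Mki67 in 78.9% of its cells, together with T cell transcripts such as Cd3e in 7.39%. In cluster 10, counted as cycling by its replication genes, Mki67 was in 3.39% and Top2a in 7.08% of cells, and in cluster 7, not counted, Mki67 was in 7.56%. With at least 2 G2 and M phase genes per thinned cell as the measure, the difference was 2.10 points (exact permutation p = 0.25).

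Across the 12 authors' clusters, 0 shares differed with AL002c after adjustment by the exact permutation test, 5 clusters of 12 had an unadjusted p under 0.05, and the smallest adjusted p was 0.0556. The smallest p of this test, 0.00926, cannot pass adjustment over 12 clusters unless several clusters have a p at or near it. The count of 0 therefore reflects a limit of the design and does not show that shares were alike. An edgeR test of cell counts per cluster, added after the data were seen, called 3 of the 12. Single cluster shares are not compared between the groups here, because leading genes of many clusters were themselves called in R47H mice: of 10 each, 9 higher in cluster 7, 3 in cluster 9, 10 in cluster 11, 7 in cluster 6, 4 in cluster 10 and 7 lower in cluster 1. With log odds of the share 3 clusters were called, and with cells of at least 1000 UMIs 5 were. Clusters rebuilt without 3451 defining or called genes gave 15 clusters, of which 0 were called and 3 had an unadjusted p under 0.05. Rebuilt with all genes, 0 of 22 were called and 7 had an unadjusted p under 0.05. The 0 called therefore does not show what leaving those genes out did.

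Within clusters fewer genes were called than over all microglia. In cluster 3, led by Spp1, Lpl and Apoe, Apoe itself fell by 0.52 (± 0.05, adjusted p = 9.32e-07) on average over the genotypes. In R47H mice it fell by 0.92 (adjusted p = 1.15e-10), so the average leans on those mice. In cluster 8, also led by Lgals3 and Spp1, Ccl12 rose by 1.17 ± 0.17 (adjusted p = 0.000718). In cluster 6, led by Ifit3 and Isg15, Cd74 rose by 0.90 ± 0.15 (adjusted p = 0.0127) and Ifi27l2a by 0.45 ± 0.09 (adjusted p = 0.0424). In cluster 5, Ifi27l2a rose by 1.32 ± 0.24 (adjusted p = 0.0122), Cenpf by 3.01 ± 0.61 (adjusted p = 0.0377) and Cd52 by 0.43 ± 0.09 (adjusted p = 0.0424). Cd52 also rose in cluster 0 (0.29 ± 0.05, adjusted p = 0.0158). Averaged over the genotypes, 9, 0, 1, 2, 1, 7, 5 and 1 genes were called in clusters 0 to 6 and 8, against 17, 25, 16, 19, 6, 32, 13 and 2 in R47H mice. In cluster 1 the averaged count was 0 by edgeR (556 at an unadjusted p under 0.05) and 11 with at least 50 cells per animal. Clusters 7, 9, 10 and 11 had too few cells per animal to be tested.

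Other CD45 positive cells were compared in the full tables. Of the 47445 barcodes, 31226 were microglia-like, 1764 neutrophil-like, 1612 T cell-like, 1331 B cell-like, 1005 monocyte-like, 803 NK or innate lymphoid cell-like and 483 dendritic cell-like. A class with transcripts of both microglia and border-associated macrophages was larger than each of these but the microglia-like class, with 2082 barcodes. A further 5565 barcodes stayed unnamed and were not among the 14 classes tested. T cell-like cells made up 2.23% ± 0.0731 of CV AL002c (n = 2), 4.33% ± 0.988 of CV isotype (n = 2), 3.36% ± 0.810 of R47H AL002c (n = 4) and 3.45% ± 0.779 of R47H isotype barcodes (n = 3). Neutrophil-like cells made up 1.43% ± 0.451, 1.40% ± 0.364, 2.90% ± 1.99 and 5.03% ± 3.66 in the same order. None of 14 classes differed with AL002c by the exact permutation test, with 0 at an unadjusted p under 0.05, a smallest p of 0.139 (a class with transcripts of both microglia and neutrophils) and a smallest adjusted p of 0.987.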

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

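The tests chosen only after the result was seen were the filter on rare markers, the reading of the thinned share, itself planned, as a test of depth, the comparison of the runs, the reading of the run A count, also planned, as a test of the run, the neighbours of the MHC class I genes and the counts over other splits of the animals; the other tests of this part were set before their results were seen.

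All 37 genes whose AL002c effect differed between the genotypes were singled out by the test of that difference, and 12 of them were named by rule. Their differences, R47H minus CV on the log2 scale, were 1.85 for Hmmr, 1.85 for Cdkn1a, 1.62 for Cenpe, 1.59 for Cenpa, 1.58 for Birc5, 1.51 for Cenpf, 1.46 for Racgap1, 1.41 for Cdca8, 1.23 for Stmn1, 1.08 for Mki67, 0.94 for Tmsb10 and 0.93 for Ramp1. Most of these genes act in mitosis, while Tmsb10 binds actin and Ramp1 is part of a neuropeptide receptor.

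A single animal lay far from the other 3 of its group for 8 of 183 values (4.37%). Chance gives about 1 in 20 if the animals of the group are alike, but these came from both runs, so that rate is only a rough guide. The R47H AL002c group was the 1 group with 4 animals and so the 1 that could be looked at. R47H AL002c animal 48 held 885.0 CPM of S100a8 and S100a9 together in its microglia against 90.8, 95.5 and 96.3 in the other 3, 10.9 CPM of haemoglobin transcripts against 0, 0.183 and 1.20, 1.45 CPM of Hbb-bs against 0, 0 and 0.199 and 2.14 CPM of Hbb-bt against 0 in each of the others. R47H AL002c animal 7 had 56.1 CPM of the interferon gene Isg15. R47H AL002c animal 8 had 263.2 CPM of the glycolytic gene Aldoa, 21.6 CPM of the ribosome biogenesis gene Rrp9 and 4.20% of its microglia in cluster 6, the interferon cluster.

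The first pattern was the rise of Mki67, Top2a and other cycle genes with AL002c. Cells of another type that divide could bring such transcripts. Leaving out every cell with any UMI of 35 lymphocyte and neutrophil markers left 3.16% of the microglia and a difference of 7.12 points (exact permutation p = 0.130), so with this filter the explanation cannot be told apart from division of microglia, because too few cells remained. Leaving out instead the 3496 cells with a marker seen in under 3% of microglia gave 3.31 points (exact permutation p = 0.00926, the smallest possible), which argues against such cells as the whole source. Deeper cells are argued against by the 3.29 points after thinning, and a difference between runs by the 553 genes higher within R47H run B alone (2 against 2 animals). Of the genes higher in R47H run A 96.9% were also higher in run B, although the run A calls rest on 1 isotype animal, animal 10, assumed to vary like the others. Division of microglia after AL002c stays a hypothesis, and free RNA from other dividing cells stays open.

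The second pattern was the larger effect in R47H mice. Fewer animals and cells in CV mice could hide an equal effect, but over the 553 genes called higher in R47H run B the median in CV mice was 0.277 of that in R47H run A, where R47H isotype animal 10 stands alone and is assumed to vary like the others (0.10 against 0.36; fry p of the difference = 0.00729, 2-sided). Without animal 10 the test of the difference over all other animals called 47 genes, all higher in R47H. A difference between the runs cannot be told apart: run A alone called 23 genes but rests on animal 10, and without it the R47H effect comes from run B alone. With 2 CV animals per group, an animal-specific cause stays open, and how the 2 TREM2 variants would bring it about was not tested.

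The third pattern was the lower level of Pdcd1, Axl, DAM and MHC class I genes in R47H mice. A smaller share of cluster 3 could produce it. Without that cluster 23 of the 24 genes named for the genotype stayed called and their median effect was 0.936 of that with it. Those 24 include 12 genes that were higher in R47H mice and so are no part of the pattern. Cluster 8, with Lgals3, Spp1 and Apoe among its leading genes, stayed in. A smaller share of such cells outside cluster 3 was not tested. Over all cells both DAM lists were lost with an estimated correlation, which was not applied without or within cluster 3. With the preset correlation both stayed lower without cluster 3 (camera adjusted p = 1.22e-06 for stage 1 and 2.99e-11 for stage 2). Within cluster 3 they were not called (0.872 and 0.944), although 71 genes were. A chromosome segment linked to the transgene could also produce it, but the fullest window of 20 Mb held 3.92% of the called genes (14 of 357; permutation p = 0.383 over 10000 shuffles of the calls, 1-sided). For the MHC class I part this says little, since 6 of its 7 called genes lie on chromosome 17; there 1.15% of 174 tested neighbours were called against 2.76% of other genes (exact p = 0.954, 1-sided), but a local difference in the class I genes themselves needs no neighbours, so for them it cannot be told apart from an effect of the variant. Transgene insertion, expression level of the transgene and litter may go with the genotype and stay open beside an effect of the variant.

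Regrouping the animals gave as many genes for the averaged antibody effect in 1 of 99 splits, the real one (281, highest other 199). Splits that kept the R47H groups and exchanged CV animals gave 199, 184 and 37 genes, so this count carries the R47H effect. These splits disregard the run, and under 1 in 20 gave as many genes. That argues against chance for an antibody effect as a whole, but not for its CV part. Without regard to the run or the antibody, the real split alone gave as many genes for R47H mice, 1 of 34 (953, highest other 421). The same held for the genotype, 1 of 34 (358, highest other 19). For the difference of effects 4 of 99 splits gave as many (37, highest other 281), which is under 1 in 20. The other 3 kept the R47H groups and exchanged CV animals, so these counts carry the R47H effect, a structure of the samples. With the number of AL002c animals kept in each run, 1 of 100 splits gave as many genes for the averaged effect (highest other 199) and 8 of 100 for the difference (highest other 281), so for the difference chance was not excluded. For R47H mice 18 splits keep the runs, too few for a share under 1 in 20 (953, highest other 421). The genotype splits were all within run A, and 18 of them keep the antibodies in balance, again too few (358, highest other 16).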

How the results depend on the processing

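Chosen only after seeing the data were the removal of cluster 3, of clusters 4, 8 and 9, of clusters 7, 9, 10 and 11 and of cells with marker transcripts, cluster 9 added to the cycling share, other size factors for the lists, and each alternative of the thinned share. The others were planned. Over 178 results, 2483 of 3067 values under an alternative (81.0%) counted as the same, 10 as reversed and 574 changed otherwise. The same meant the same side of the threshold or, for counts, an equal or similar number. A change of sign counted as reversed only where the main or the alternative value passed the threshold, so other changes of sign are among the same. Except where stated, the cause was not tested. Without a term for the run, 2 genes were called for the averaged effect, 64 in R47H mice and 1 for the difference. DESeq2 called 15 in CV mice and 109 for the difference. With no filter on low counts, 731 were called for the averaged effect, 166 in CV mice, 379 for the difference and 874 for the genotype. At a mean log2 CPM of at least 4, where fewer genes are tested, there were 107 on average and 593 in R47H mice. Run A alone, with fewer animals, gave 71, 145 in R47H mice and 23 for the difference. Without clusters 10 and 11, the counts were 110 on average and 21 for the difference. Without clusters 4, 8 and 9, 8 genes were called for the difference. Without clusters 7, 9, 10 and 11, 11 on average, 86 in R47H mice, 0 for the difference (edgeR) and 5 lists in CV mice. These clusters were picked because they had grown with AL002c, so lower counts are partly built into that setting. With an estimated correlation 0 lists were called in each of the 5 contrasts, and by fry 1 on average, 0 in CV mice, 7 in R47H mice, 1 for the difference and 9 for the genotype. With cells of at least 1000 UMIs 5 cluster shares were called, with log odds 3, and with at least 50 cells per animal 11 genes within cluster 1. The cycling share was 4.21 points with cluster 9 added (exact permutation p = 0.00926, the smallest possible), against 2.04 without it, 2.10 with 2 or more G2 and M phase genes and 2.71 without cells with any marker (exact permutation p = 0.0833), and the thinned share 7.12 without those cells.

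Reversed in direction were, for the genotype without a term for the run, S phase (camera adjusted p = 0.101), G2 and M phase (1.4e-06), RNA quality (0.984) and oxidative phosphorylation (nuclear-encoded oxidative phosphorylation, R47H against CV averaged over both antibodies: 0.263, and over animals left out 0.000679 to 0.426, the highest without R47H isotype animal 10). For the averaged effect S phase reversed without clusters 10 and 11 (0.0178) and without clusters 7, 9, 10 and 11 (0.331), where Ccnb2 was at -0.15 and Cdca8 at -0.0116. Both settings leave out clusters led by cycle genes, so a loss of the rise of cycle genes is partly built into them. The cluster 2 share was -0.329 points when permuted within genotype only. Leaving out 1 animal gave 156 to 300 genes on average, 0 to 6 in CV mice, 493 to 957 in R47H mice, 12 to 53 for the difference and 143 to 368 for the genotype. It gave 8 to 13, 3 to 8, 9 to 12, 8 to 12 and 12 to 17 lists in that order, a cycling share of 1.76 to 2.50 points, a thinned share of 2.64 to 3.63, and 0 to 0 cluster shares and 0 to 0 CD45 classes, where the few permutations limit what can pass. Where an arm was left with 1 animal, edgeR pooled the spread, so that animal was assumed to vary like the others. On simulated changes fewer were found in CV than in R47H mice at each fold, and depth was not separated from the number of animals there.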

Other observations

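The genes of the first 2 paragraphs were chosen after their values were seen, as was the p53 hypothesis; its test on other genes was set before their values were looked at.

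Beyond the cycle, several genes outside the lists had a larger AL002c effect in R47H than in CV mice. Prdx4, a peroxiredoxin of the endoplasmic reticulum, differed by 0.88 ± 0.07 (log2, SE; edgeR adjusted p = 0.000195), and Tspo, the mitochondrial protein used as a PET marker of glia, by 0.62 ± 0.09 (edgeR adjusted p = 0.0105). The actin-capping gene Capg (0.58 ± 0.10, edgeR adjusted p = 0.0286), the membrane protein gene Emp3 (0.81 ± 0.14, edgeR adjusted p = 0.0262), Il3ra, the interleukin-3 receptor alpha chain (1.15 ± 0.18, edgeR adjusted p = 0.0206), and Igfbp4, which binds insulin-like growth factors (0.88 ± 0.15, edgeR adjusted p = 0.0262), also differed. Prdx4 and Igfbp4 are leading genes of cluster 7, as are Ramp1 and Cdkn1a, while Tspo, Capg, Emp3 and Il3ra are not. With clusters 7, 9, 10 and 11, picked because they had grown with AL002c, left out together, no gene was called by edgeR for the difference. Cluster 7 was not left out alone. More cells of that kind therefore cannot be told apart from a rise within cells. In CV mice the AL002c effect was 0.14 for Prdx4, 0.01 for Tspo and 0.03 for Capg, and in R47H mice 1.02, 0.63 and 0.60.

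Inhibitors of the cycle were among these genes too. Cdkn2a, which codes for p16 and p19ARF, had a difference of 1.64 ± 0.28 (edgeR adjusted p = 0.0262), and the p53 targets Phlda3, Bbc3, the gene of PUMA, and Rps27l had differences of 2.97 ± 0.52 (edgeR adjusted p = 0.0313), 0.77 ± 0.12 (edgeR adjusted p = 0.0246) and 0.41 ± 0.07 (edgeR adjusted p = 0.0336). A p53 response to AL002c in R47H mice was a candidate explanation. It was tested on 21 textbook p53 targets other than these 3 and Cdkn1a. Their median in R47H mice was 0.111 (fry p = 0.0245, 2-sided; camera p = 0.00374, but 0.162 with an estimated correlation), just above the 0.1 set for it, and 17 of 21 were positive. Of these 3 rose by edgeR, Bax (0.40, adjusted p = 9.34e-05), Trp53inp1 (0.41, adjusted p = 0.0153) and Ccng1 (0.41, adjusted p = 0.0206), and 5 when adjusted over the list alone. In CV mice the median was 0.03, which did not pass fry. The difference between the genotypes had a median of 0.06 and did not pass fry either, so it was not shown. A small rise of p53 targets in R47H mice therefore stays a hypothesis.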
